A study of Mus musculus with 12 samples.

How the data were processed

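Messenger RNA was measured in 12 libraries of splenic CD8 T cells from female C57BL/6 mice, 3 libraries in each of 4 groups (WT and KO, day 3 and day 5), with group and replicate taken from the sample titles. Per the labels' protocols, naive cells were stimulated for 2 days with immobilised antibody to TCR-β (3 µg/ml) and antibody to CD28 (1 µg/ml) in IL-2 (10 ng/ml). They were then moved to a new plate in IL-2 for 1 or 5 days. Those times add up to day 3 and to a later day than the day 5 of the titles, and the labels do not settle this, so "day 5" follows the titles. RNA was extracted with an RNeasy kit, and 500 ng of total RNA went into QuantSeq 3′ mRNA libraries, per the labels' protocols. Such libraries give tags near the 3′ end of polyadenylated transcripts, so a gene's value does not scale with its length and splice forms cannot be told apart.

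The deposited files name their values TPM, but each column sums to 1000000 and 100% of values are whole multiples of one step within 0.001 read, which per-length scaling would not give. The deposited values are therefore treated as CPM, made by the authors by dividing each gene's whole reads by the library total. The design written before the data were examined assumed TPM. The test it names was kept, on log2(CPM + 1). The submitters' processing notes name the builds GRCm39 and mm10 without saying what each was used for. The aligner, the counting tool, the annotation and whether counting used strand are not given in the sources used here. Reads of near copies (Gzmd to Gzmg, Hba-a1 and Hba-a2, Klra and H2 genes) and of overlapping or antisense genes may therefore be divided in an unknown way. The files pair each gene name with an Ensembl identifier. Of 25655 identifiers, 25600 were found in GENCODE M21, which is on GRCm38, and coordinates come from that annotation, not from the files. The number of columns of other samples was 0. Of 494 immunoglobulin and T cell receptor genes listed, 0 had a read in any library, so values of 0 for such list members carry no information on the cells.

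Whole reads were recovered from the CPM steps. Libraries held 1545391 to 2011247 reads, so 1 read was worth 0.497 to 0.647 CPM. A count of 0 over the 3 libraries of a group allows 0.571 CPM in WT day 3, 0.527 in KO day 3, 0.569 in WT day 5 and 0.632 in KO day 5, taking 3 reads as the floor. These floors cover counting error only. A fold against a group with no read was computed against that floor and is a lower bound. No fold is given against a group with 1 to 3 reads.

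Genes with CPM of at least 1 in at least 3 libraries were tested (11417 genes, 14238 not tested). log2(CPM + 1) values computed here from the deposited CPM were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group, empirical Bayes moderation with a trend on expression and 21.1 total degrees of freedom. The tests are moderated, two-sided and adjusted by Benjamini-Hochberg over all genes of a comparison, with a threshold of 0.05. The comparisons were KO against WT at each day, day 5 against day 3 in each genotype, and the genotype by day interaction. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Of 25 lists, 23 had the 3 tested members required. The lists cover PRC2 members, H3K27me3-linked developmental and cell cycle inhibitor genes, terminal effector, memory precursor, cytotoxic, inhibitory receptor, NK receptor, cytokine, helper and regulatory, S and G2/M, p53 response, glycolysis, oxidative phosphorylation, cholesterol synthesis, interferon-stimulated, trafficking, immediate early and mitochondrially encoded genes. They also hold markers of B, CD4 T, CD8 T, gamma delta or MAIT or NKT, myeloid and dendritic, erythroid and platelet, and stromal and endothelial cells. Several genes stand in more than 1 list. The overlap of calls at the 2 days used a one-sided Fisher's exact test.

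The tests, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule takes Ezh2, the 12 largest rises and falls of each genotype comparison and the 6 of each day comparison. These need a mean of at least 5 CPM in the higher group, no overlap between the groups' libraries and a symbol that is not a predicted model. For the interaction it takes the 5 smallest adjusted p in each direction. It adds the 4 members of each list with the smallest adjusted p, and members of counts of 5 or fewer. The text leaves out some of these. Klrg1, the levels at each day beside interaction results and the genes plotted by library were chosen after their values were seen.

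Alternatives were pseudocounts of 0.1 and 5, no filter or CPM of at least 5, median-of-ratios scaling, quantile normalization, the replicate number as a block, moderation without trend or with a robust prior, only the libraries compared, a 2-fold minimum, fry in place of camera and leaving out each library in turn. Added after the data were seen were edgeR 4.0.16's quasi-likelihood test with TMM scaling on the recovered reads, thinning of every library to 1545391 reads and counts of list members without each library. Such a count is given where it moved by over 1.5 times and the larger count was at least 5. All groups share each gene's spread estimate, so leaving out a library can also move counts of comparisons it is not part of. Files were read with the R package data.table (version 1.17.8), and the random seed was 20261. The steps were tested on simulated data for the day 3 comparison with 200 genes changed and a dispersion of 0.01. Of the 11420 genes that passed the filter, 67, 67 and 65 were changed 1.5, 2 and 4-fold. limma called 26.9% of genes changed 1.5-fold, 65.7% of those changed 2-fold and 86.2% of those changed 4-fold, and 3 of 11221 unchanged genes. edgeR called 32.8%, 67.2% and 86.2%, and 1 unchanged gene. camera called 0 of 24 unchanged sets, but genes were simulated independently, so this does not test lists of correlated genes. A simulation of the day 5 comparison with no change gave 0 calls by limma over 11420 genes. Every library was simulated with the same dispersion, so a library that stands apart, such as KO day 5 replicate 2, is not covered.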

Results

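The study measured messenger RNA in CD8 T cells from the spleens of female C57BL/6 mice that were wild type (WT) or deficient in Ezh2 (KO). Ezh2 is a catalytic subunit of Polycomb repressive complex 2 (PRC2), which places the repressive chromatin mark H3K27me3. Naive cells were activated through the T cell receptor and CD28 in the presence of IL-2 and then kept in IL-2 alone. The titles place 3 libraries in each of 4 groups, WT and KO at day 3 and WT and KO at day 5. The title of the series asks about Ezh2 in short-lived effector differentiation of CD8 T cells and in tumour immunity. The libraries hold tags from the 3′ ends of polyadenylated transcripts, between 1545391 and 2011247 gene-assigned reads each. Between 11257 and 11973 genes were detected per library. Values are in CPM, the reads of a gene per 1000000 reads of its library. They are given as mean ± SD with n = 3 libraries per group. Fold changes on the log2 scale were computed on log2(CPM + 1), which understates the change of low genes, and are given with their standard error (SE). Of 25655 genes listed, 11417 passed the expression filter and were tested with limma. The labels do not say whether replicates came from separate mice or cultures. The p-values therefore measure the spread between these libraries, which may be technical.

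The targeted gene was examined first. Ezh2 (ENSMUSG00000029687, chromosome 6, 47530139 to 47595341, minus strand, GRCm38) stood at 357, 374 and 409 CPM in the WT day 3 libraries and at 377, 334 and 311 CPM in the KO day 3 libraries. At day 5 the WT libraries held 306, 319 and 316 CPM and the KO libraries 159, 283 and 161 CPM. The genotypes did not differ at day 3 (log2 fold change −0.16 ± 0.15 SE, limma adjusted p = 0.499), and Ezh2 fell in KO at day 5 (−0.70 ± 0.15 SE, limma adjusted p = 5.83e-04). A tag from the 3′ end outside the deleted part of the gene checks nothing, and the deleted part is not given in the sources used here. These values neither test the genotype labels nor measure the loss of the protein. Replicate 2 of KO day 5 was the highest KO library at that day, and without it the log2 fold change was −0.97.

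**Figure D1:**
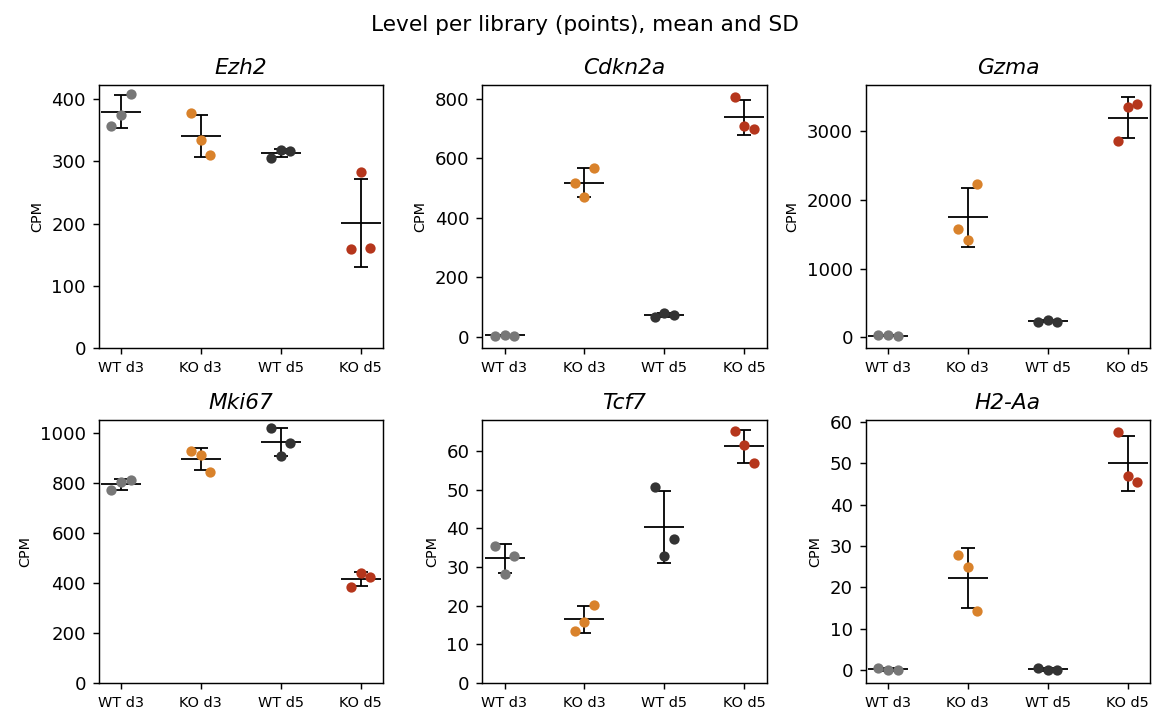
Level in CPM of 6 genes in each of the 12 libraries (points), with the group mean and SD (n = 3). Cdkn2a and Gzma were higher in KO at both days, Mki67 stood at 416 ± 29.1 CPM in KO at day 5 against 963 ± 56.5 in WT, and Tcf7 was lower in KO at day 3 and higher at day 5.

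Libraries grouped by genotype and day. The first principal component, with 44.9% of the variance, ran from −44.5 in WT day 3 to 59.5 in KO day 5, with KO day 3 between 2.88 and 9.66 and WT day 5 between −21.3 and −20.5. Replicate pairs differed by more than read sampling in every group (chi-square per degree of freedom from 1.33), so no library was counted as a copy of another. KO day 5 replicate 2 stood apart from its group, with a chi-square per degree of freedom of 5.89 and 5.69 against its partners where no other pair exceeded 2.56. It scored 34.5 on the fourth component against −21.0 and −21.6, and mitochondrial transcripts made up 2.07% of its reads against 3.00% and 3.12%.

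The comparison of genotypes at day 3 asked how the libraries labelled KO differed from WT soon after activation. KO cells held 137-fold more Cdkn2a (ENSMUSG00000044303, chromosome 4, 89274471 to 89294653), the gene of the cell cycle inhibitors p16 and p19 and a classical Polycomb target, at 518 ± 49.2 CPM against 3.77 ± 2.57 in WT (log2 fold change 6.90 ± 0.22 SE, limma adjusted p = 8.25e-16). Gzma (ENSMUSG00000023132, chromosome 13, 113093825 to 113100981), which encodes a granule protease of killer cells, rose 74.4-fold to 1744 ± 434 CPM (6.17 ± 0.16 SE, limma adjusted p = 1.74e-17). The transcription factor gene Maf rose 39.2-fold, the antiviral membrane protein gene Ifitm1 22.6-fold to 953 ± 122 CPM, and the cytokine gene Il10 26.9-fold to 77.4 ± 13.2 CPM. Msc, Esm1, Itsn1 and the nuclear lamin gene Lmna rose 43.1, 24.6, 19.0 and 17.4-fold. Khdc1a, with no read in WT, was at least 25.1-fold higher against a floor of 3 reads over the group. H2-Aa and Onecut2 reached 22.3 ± 7.16 and 17.8 ± 4.53 CPM in KO from 1 read each over the WT group. Genes that fell included Dapl1 (9.79-fold lower), Ncf1 (11.0-fold), Capn3 (12.5-fold), the orphan receptor gene Nr4a3 (9.18-fold), the costimulatory receptor gene Tnfrsf4 (5.92-fold), and the T cell surface receptor genes Cd6 (3.76-fold) and Cd5 (3.09-fold).

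In total 2100 genes differed at day 3, 1275 higher and 825 lower in KO. A change of at least 2-fold was seen in 673 and 94 of them. Of 23 testable gene lists fixed before the data were examined, 15 passed camera with its preset correlation and 7 did with an estimated one. Camera adjusted p also rose where the estimated correlation was negative, so below the preset one. It went from 3.31e-07 to 0.00353 for H3K27me3-linked genes (−0.041) and from 0.0349 to 0.0853 for cytokines (−0.018). Of such lists only cholesterol synthesis genes (−0.012) went the other way (0.421 to 0.41). A call lost with an estimated correlation thus does not show that a list's genes are correlated, and the cause was not tested. With fry, which does not set a list against the other genes, 16 passed. It added memory precursor (fry adjusted p = 0.016, down), inhibitory receptor (9.94e-05, up) and NK receptor genes (0.0405, up). It lost oxidative phosphorylation genes (0.0546) and mitochondrially encoded mRNAs (0.0624). Counts of list members below are over all genes tested, with the count adjusted over the list alone beside them. Where a pair of camera adjusted p-values is given, the first is with the preset correlation and the other with an estimated one.

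Cytotoxic granule and killing genes rose together at day 3. Of 23 tested members 19 rose and none fell (20 rose when adjusted over the list alone), with camera adjusted p = 5.34e-18 and adjusted p = 0.00702 with an estimated correlation. Prf1, the pore-forming perforin, stood at 453 ± 107 CPM in KO against 51.9 ± 6.78 in WT, the protease gene Ctsd at 393 ± 41.3 against 113 ± 11.1, and the granule proteoglycan gene Srgn at 236 ± 9.34 against 116 ± 12.6. Among terminal (short-lived) effector genes 15 of 31 rose and 2 fell (19 and 2 adjusted over the list alone, camera adjusted p = 1.58e-15, adjusted p = 0.00353 with an estimated correlation). S100a6 rose from 291 ± 11.0 to 2528 ± 259 CPM, S100a4 from 64.8 ± 10.1 to 579 ± 79.5, and Lgals3 from 101 ± 11.1 to 675 ± 140. The members that fell were Tbx21, which encodes T-bet, a transcription factor of the short-lived effector fate (37.8 ± 5.86 to 22.7 ± 0.226 CPM, log2 fold change −0.70 ± 0.16 SE, limma adjusted p = 0.00433), and Klrk1, the NKG2D receptor gene (79.4 ± 4.31 to 27.7 ± 2.72 CPM). Klrg1, the usual surface marker of that fate, was not tested, with no read in the WT groups and 1 and 2 reads in the KO groups at day 3 and day 5.

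Memory precursor and stem-like genes went both ways at day 3, with 4 of 29 higher and 9 lower (4 and 10 adjusted over the list alone). The list did not pass (camera adjusted p = 0.196, direction down, while its median log2 fold change was 0.17). Ltb fell from 161 ± 8.47 to 81.5 ± 15.4 CPM and Cd27 from 82.3 ± 3.56 to 40.5 ± 3.73, while Eomes rose from 89.8 ± 4.34 to 116 ± 9.75 CPM. The Eomes call ended when the spread was fitted without its trend on expression (limma adjusted p = 0.0725) and without WT day 3 replicate 3 or KO day 3 replicate 1 or 2 (0.0628, 0.0711 and 0.0501). Helper and regulatory lineage genes had 8 of 14 higher and 2 lower (the same counts adjusted over the list alone, camera adjusted p = 0.00107, adjusted p = 0.0484 with an estimated correlation), and 5 higher without KO day 3 replicate 2. Rora rose with Maf, from 26.8 ± 0.827 to 63.6 ± 5.38 CPM, and Irf4 fell from 132 ± 12.6 to 78.5 ± 7.41. Inhibitory receptor genes had 6 of 20 higher and 3 lower (9 and 5 adjusted over the list alone) without passing as a list (camera adjusted p = 0.12). Havcr2, encoding TIM-3, rose from 4.97 ± 1.56 to 35.2 ± 7.09 CPM and Cd160 from 23.5 ± 3.94 to 75.0 ± 7.23.

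Of 45 developmental and cell cycle inhibitor genes commonly under H3K27me3 only 10 passed the expression filter, and 8 of them rose and none fell (8 adjusted over the list alone, camera adjusted p = 3.31e-07, adjusted p = 0.00353 with an estimated correlation). The count was 5 with quantile normalisation, and 5 without KO day 3 replicate 1 or any 1 of the WT day 3 libraries. Members with few or no reads in WT can pass the expression filter only when KO libraries are high. The filter therefore favours rises in this count, at day 5 as well, and in other lists with members near 0 in WT, such as the myeloid markers. Beside Cdkn2a, the inhibitor gene Cdkn2b reached 16.9 ± 3.50 CPM from 2 reads over the WT group, Sox4 rose from 2.47 ± 0.323 to 12.8 ± 1.89 CPM, and Lhx2 reached 4.39 ± 0.573 CPM. Of the PRC2 genes themselves 2 of 12 rose and 3 fell (2 and 4 adjusted over the list alone, camera adjusted p = 0.672; median −0.12 and mean 0.11). Jarid2 rose from 61.1 ± 5.37 to 126 ± 6.21 CPM and Suz12 fell from 729 ± 41.1 to 563 ± 23.1.

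p53 response and apoptosis genes had 14 of 26 members higher and none lower (15 adjusted over the list alone, camera adjusted p = 1.96e-09, adjusted p = 0.00241 with an estimated correlation). The pro-death BH3 gene Bcl2l11 rose from 43.7 ± 6.78 to 89.1 ± 2.28 CPM, and Ccng1 from 80.4 ± 5.86 to 156 ± 8.05. S and G2/M phase genes had 11 of 45 lower and none higher (13 adjusted over the list alone, camera adjusted p = 2.53e-07), a list call lost with an estimated correlation (adjusted p = 0.0597 with an estimated correlation). Top2a fell from 2840 ± 45.8 to 2264 ± 88.4 CPM and Cdc6 from 133 ± 8.09 to 86.4 ± 3.13. Without KO day 5 replicate 2 the counts were 20 lower and 1 higher, and without WT day 3 replicate 2 the number lower was 6. Trafficking and adhesion genes had 13 of 26 higher and 2 lower (14 and 3 adjusted over the list alone, camera adjusted p = 8.79e-06, adjusted p = 0.00804 with an estimated correlation). The chemokine receptor genes Ccr2 and Cxcr6 rose to 206 ± 7.63 and 83.8 ± 19.8 CPM from 46.8 ± 3.79 and 10.4 ± 3.49, and Cd44 from 132 ± 10.8 to 246 ± 18.1.

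Markers of other cell types moved with these groups. Of 17 tested myeloid and dendritic cell markers 9 were higher in KO and none lower (12 and 1 adjusted over the list alone, camera adjusted p = 1.49e-07, adjusted p = 0.00353 with an estimated correlation). They included Ccr2, H2-Eb1 (0.571 ± 0.0195 to 10.9 ± 3.31 CPM) and the invariant chain gene Cd74 (0.953 ± 0.337 to 14.7 ± 6.21 CPM). Of 7 erythroid and platelet markers 3 were higher (3 adjusted over the list alone, camera adjusted p = 0.0418, adjusted p = 0.27 with an estimated correlation). They include the haemoglobin genes Hba-a1, at 7.07 ± 2.77 CPM from 1 read in WT, and Hba-a2, near copies whose reads may be shared. This list call ended without WT day 3 replicate 1 or 3 or KO day 5 replicate 2 (adjusted p of 0.0617, 0.0862 and 0.0525), and the Hba-a2 call without KO day 3 replicate 3 or WT day 3 replicate 1 or 3 (limma adjusted p of 0.131, 0.0731 and 0.0596) and without the trend in the spread (0.0657). Among 9 CD8 T cell markers 4 were lower in KO, led by Cd2 (473 ± 18.4 to 244 ± 4.77 CPM). Cd8a stood at 242 ± 21 against 323 ± 29.2 CPM (4 adjusted over the list alone, camera adjusted p = 0.00482, adjusted p = 0.238 with an estimated correlation). The Cd8a call ended when the spread was fitted without its trend (limma adjusted p = 0.0517).

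The remaining lists were tested in the same way at day 3. Cytokines and chemokines had 5 of 19 higher and 2 lower (5 and 2 adjusted over the list alone, camera adjusted p = 0.0349, adjusted p = 0.0853 with an estimated correlation). Ccl5 stood at 79.3 ± 13.9 against 19.2 ± 1.23 CPM and Lta at 234 ± 54.0 against 434 ± 45.3. The cytokine list call ended with quantile normalisation (camera adjusted p = 0.0617) and with only the libraries compared (0.0551). It also ended without any 1 of several libraries (up to 0.0595, without WT day 3 replicate 3). Glycolysis and hypoxia genes had 9 of 31 lower and none higher (11 adjusted over the list alone, camera adjusted p = 0.00113, adjusted p = 0.155 with an estimated correlation). The count was 4 without KO day 3 replicate 1 and 5 without WT day 3 replicate 2 or 3. Oxidative phosphorylation genes had 3 of 37 lower (2 adjusted over the list alone, camera adjusted p = 0.049, adjusted p = 0.284 with an estimated correlation), and 6 lower and 1 higher without KO day 5 replicate 2. Quantile normalisation ended this list call (adjusted p of 0.361), as did leaving out any 1 of several libraries (up to 0.131, without KO day 3 replicate 2). Mitochondrially encoded mRNAs had 6 of 13 higher (8 adjusted over the list alone, camera adjusted p = 5.35e-04, adjusted p = 0.308 with an estimated correlation), such as mt-Cytb at 2404 ± 242 against 1663 ± 24.3 CPM. CD4 T cell markers had 2 of 6 lower, Cd5 and Foxp3 (3 adjusted over the list alone, camera adjusted p = 0.049, adjusted p = 0.171 with an estimated correlation). A stricter expression filter ended this list call (adjusted p of 0.238), as did leaving out any 1 of several libraries (up to 0.0881, without WT day 3 replicate 3). The Foxp3 call ended without WT day 3 replicate 1 or KO day 3 replicate 1 or 2 (limma adjusted p of 0.0743, 0.0622 and 0.0641) and without the trend in the spread (0.0679). NK receptor genes (3 of 16 higher, 1 lower, the same adjusted over the list alone, camera adjusted p = 0.159), cholesterol synthesis genes (2 of 28 higher, 2 lower, the same adjusted over the list alone, 0.421) and interferon-stimulated genes (6 of 40 higher, 3 lower, the same adjusted over the list alone, 0.479; median 0.00) did not pass. Immediate early and heat shock genes did not pass either (2 of 23 higher, 3 lower, the same adjusted over the list alone, camera adjusted p = 0.605), and 6 were lower without KO day 5 replicate 2. Egr1 was higher in KO with a wide spread (261 ± 160 against 19.7 ± 1.74 CPM). Of 5 B cell markers 1 was higher (1 adjusted over the list alone, camera adjusted p = 0.336). Lists with under 3 tested members had no list test, namely the gamma delta, MAIT and NKT markers (1 tested, Klrb1c, not passed; 0 adjusted over the list alone) and the fibroblast, stromal and endothelial markers (2 tested, 1 higher, 2 higher when adjusted over the list alone). The member that rose was Thy1, which T cells also express (1130 ± 104 against 820 ± 32.0 CPM). Its call ended without WT day 3 replicate 1 or KO day 3 replicate 3 (limma adjusted p of 0.0556 and 0.0764), without the trend in the spread (0.111) and with a robust prior (0.0849).

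**Figure D2:**
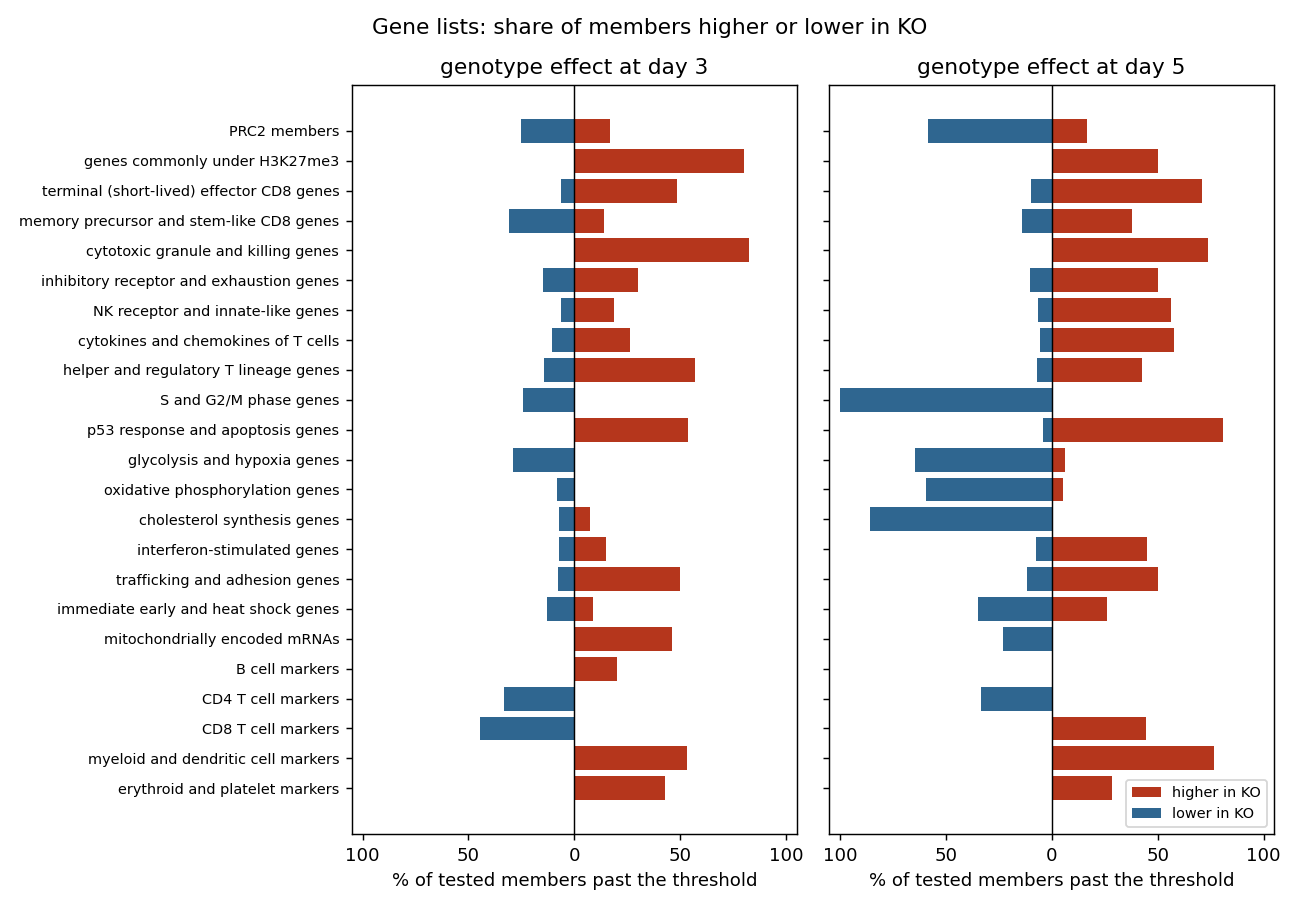
Share of the tested members of each gene list that were higher (right, red) or lower (left, blue) in KO at limma adjusted p under 0.05, at day 3 and at day 5 (n = 3 libraries per group). All 45 S and G2/M phase genes were lower at day 5, against 11 at day 3.

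The same comparison was made at day 5. All 45 tested S and G2/M phase genes fell in KO. Top2a stood at 1052 ± 73.4 CPM against 2933 ± 25.9 in WT (log2 fold change −1.48 ± 0.07 SE, limma adjusted p = 5.53e-13), the replication factor gene Mcm3 at 152 ± 2.61 against 405 ± 21.2, and the chromatin remodeller gene Hells at 85.1 ± 9.48 against 293 ± 15.5. Of the granzyme genes on chromosome 14, Gzmd (ENSMUSG00000059256, 56129556 to 56132608) reached 136 ± 22.9 CPM from 2 reads over the WT group. Gzmg (ENSMUSG00000040284, 56156582 to 56159579) was at least 175-fold higher, Gzme at least 58.0-fold and Gzmf at least 48.9-fold, and Gzmc rose 79.2-fold to 104 ± 25.9 CPM. These 5 genes are near copies of each other, so how reads were divided among them is uncertain. The class II antigen presentation genes H2-Aa and Cd74 reached 50 ± 6.63 and 55.2 ± 16.8 CPM from 1 read each over the WT group. Serpine2 rose 34.0-fold to 484 ± 40.5 CPM (4.99 ± 0.13 SE, limma adjusted p = 5.20e-17), Asb2 51.7-fold and Marcks 27.7-fold, while Lat2 and Ly6g reached 63.8 ± 1.54 and 53.6 ± 13.6 CPM from 2 reads each. Lower in KO were, among others, Dapl1 (26.4-fold, ENSMUSG00000026989, chromosome 2, 59484653 to 59505020), Hemgn (6.79-fold), the cell cycle kinase gene Pkmyt1 (9.59-fold), the secreted glycoprotein gene Stc2 (6.38-fold), Tnfrsf4 (5.11-fold) and the mitochondrial protein gene Chchd10 (4.89-fold, 33.2 ± 6.18 against 162 ± 12.4 CPM). Pdzd9, with no read in KO, was at least 8.97-fold lower.

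At day 5 4501 genes differed, 1885 higher and 2616 lower, and 939 and 776 of them by at least 2-fold. The split depended on the scaling, since 41.9% of calls were higher with the deposited scale and 52.3% with median-of-ratios scaling (2301 higher, 2098 lower). Of 23 lists 16 passed camera, and 11 with an estimated correlation. With fry 20 passed. It added PRC2 (fry adjusted p = 9.52e-06, down), memory precursor (0.00512, up), erythroid and platelet (0.00132, up) and immediate early and heat shock genes (0.00813, down).

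The S and G2/M list passed with camera adjusted p = 3.72e-32 (adjusted p = 0.00121 with an estimated correlation). The count was 45 adjusted over the list alone, 45 with median-of-ratios scaling and 45 without KO day 5 replicate 2. Cholesterol synthesis genes had 24 of 28 lower and none higher (24 adjusted over the list alone, camera adjusted p = 1.84e-11, adjusted p = 5.70e-04 with an estimated correlation). Hmgcs1 stood at 364 ± 58.0 against 794 ± 20.6 CPM and Cyp51 at 159 ± 9.0 against 382 ± 20.5. Glycolysis and hypoxia genes had 20 of 31 lower and 2 higher (the same adjusted over the list alone, camera adjusted p = 7.69e-07, adjusted p = 0.0291 with an estimated correlation). Hk2 fell from 148 ± 4.96 to 62.7 ± 11.3 CPM. Oxidative phosphorylation genes had 22 of 37 lower and 2 higher (23 and 2 adjusted over the list alone, camera adjusted p = 2.59e-04, adjusted p = 0.0665 with an estimated correlation). The ATP synthase gene Atp5b fell from 489 ± 13.2 to 279 ± 12.5 CPM, and Uqcrh rose from 340 ± 12.9 to 509 ± 11.0.

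p53 response and apoptosis genes had 21 of 26 higher and 1, Bid, lower (22 and 1 adjusted over the list alone, camera adjusted p = 1.48e-12, adjusted p = 5.70e-04 with an estimated correlation). Bcl2l11 rose from 89.7 ± 4.48 to 408 ± 25.9 CPM, Trp53inp1 from 69.9 ± 11.2 to 302 ± 27.5 and the p53 regulator Mdm2 from 56.6 ± 7.39 to 202 ± 15.5. H3K27me3-linked developmental and cell cycle inhibitor genes had 5 of 10 higher (5 adjusted over the list alone, camera adjusted p = 0.00155, adjusted p = 0.0196 with an estimated correlation). Cdkn2a stood at 737 ± 60.2 against 71.2 ± 6.62 CPM, Cdkn2b at 36.8 ± 4.40 against 6.47 ± 2.14 and Hoxb4 at 8.66 ± 2.31 against 3.03 ± 0.826. The number of members higher was 3 without KO day 5 replicate 2 or WT day 5 replicate 1. The call of Sox4 ended without WT day 5 replicate 1 or 3 or KO day 5 replicate 1 or 2 (limma adjusted p of 0.0771, 0.0852, 0.071 and 0.0736). PRC2 genes had 7 of 12 lower and 2 higher without passing as a list (7 and 3 adjusted over the list alone, camera adjusted p = 0.147), and Suz12 fell to 337 ± 29.1 from 668 ± 21.1 CPM.

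Terminal effector genes had 22 of 31 higher and 3 lower (the same adjusted over the list alone, camera adjusted p = 3.59e-11, adjusted p = 0.00917 with an estimated correlation). S100a6 stood at 4919 ± 331 against 1074 ± 27.6 CPM and Id2, a transcriptional regulator of effector cells, at 4852 ± 686 against 1207 ± 70.7. Tbx21 (23.8 ± 3.62 against 53 ± 2.35 CPM) and Klrk1 were again lower, and the third member lower, Cd48, lost its call under 16 alternatives. They include median-of-ratios scaling (limma adjusted p = 0.119), edgeR (edgeR adjusted p = 0.114) and leaving out 1 of several libraries (up to 0.312, without KO day 5 replicate 2). Cytotoxic genes had 17 of 23 higher and none lower (17 adjusted over the list alone, camera adjusted p = 3.49e-13, adjusted p = 0.0135 with an estimated correlation). Gzma stood at 3197 ± 302 against 233 ± 17.8 CPM and Prf1 at 514 ± 92.7 against 44.8 ± 8.53. Inhibitory receptor genes had 10 of 20 higher and 2 lower (the same adjusted over the list alone, camera adjusted p = 0.00102, adjusted p = 0.0155 with an estimated correlation). They included Havcr2 (48.1 ± 11.1 against 9.26 ± 1.53 CPM), Cd160, and Entpd1, encoding CD39 (35.8 ± 10.3 against 9.09 ± 0.829 CPM). NK receptor genes had 9 of 16 higher and 1 lower (the same adjusted over the list alone, camera adjusted p = 0.00155, adjusted p = 0.0695 with an estimated correlation). Fcer1g stood at 21.4 ± 7.95 against 0.764 ± 0.351 CPM and Itga1 at 17.1 ± 8.32 against 0.746 ± 0.851.

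Memory precursor and stem-like genes had 11 of 29 higher and 4 lower (the same adjusted over the list alone). As a list they lay at the threshold (camera adjusted p = 0.051, adjusted p = 0.0962 with an estimated correlation). They passed under several alternatives, with adjusted p = 0.0383 under median-of-ratios scaling and 0.0296 without KO day 5 replicate 2. Lef1 rose from 113 ± 1.03 to 262 ± 54.9 CPM, Satb1 from 357 ± 19.4 to 631 ± 130 and Foxo1 from 92.0 ± 5.83 to 157 ± 14.4, while Ccr7 fell from 98.1 ± 10.6 to 38.3 ± 7.05 and Id3 from 22.5 ± 4.80 to 7.19 ± 1.95. Cytokine and chemokine genes had 11 of 19 higher and 1, Lta, lower (the same adjusted over the list alone, camera adjusted p = 1.85e-04, adjusted p = 0.00948 with an estimated correlation). Ccl5 stood at 206 ± 12.9 against 28.9 ± 6.11 CPM and Spp1, encoding osteopontin, at 54.9 ± 10.1 against 6.43 ± 1.71. Helper and regulatory genes had 6 of 14 higher and 1 lower (the same adjusted over the list alone, camera adjusted p = 0.0167, adjusted p = 0.0918 with an estimated correlation). Maf stood at 348 ± 26.7 against 23.8 ± 8.21 CPM. Trafficking genes had 13 of 26 higher and 3 lower (the same adjusted over the list alone, camera adjusted p = 2.74e-04, adjusted p = 0.0164 with an estimated correlation), and 8 higher without WT day 5 replicate 2. The integrin gene Itgb3 stood at 99.4 ± 4.87 against 18.4 ± 4.82 CPM. Interferon-stimulated genes had 18 of 40 higher and 3 lower (18 and 4 adjusted over the list alone, camera adjusted p = 4.25e-04, adjusted p = 0.157 with an estimated correlation). Mx1 stood at 46.4 ± 5.77 against 5.11 ± 1.94 CPM, and Iigp1 fell to 70.3 ± 19.5 from 167 ± 27.8.

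Myeloid and dendritic cell markers had 13 of 17 higher and none lower at day 5 (13 adjusted over the list alone, camera adjusted p = 2.55e-09, adjusted p = 0.00121 with an estimated correlation), and 12 of 16 without KO day 5 replicate 2. H2-Aa, Cd74, Ly6g and H2-Eb1 led them. The CD8 T cell markers Cd3g (276 ± 45.1 against 129 ± 5.19 CPM), Cd3d, Cd3e and Cd8a (307 ± 36.4 against 228 ± 6.92 CPM) were higher and no member was lower (4 and 1 adjusted over the list alone, camera adjusted p = 0.0191, adjusted p = 0.259 with an estimated correlation). The list call ended without KO day 5 replicate 2 (adjusted p of 0.112). Of 7 erythroid and platelet markers 2 were higher (2 adjusted over the list alone, camera adjusted p = 0.0545), Car2, at 29.4 ± 5.31 CPM against 0.569 ± 0.0139, and Hba-a1, whose call ended without KO day 5 replicate 2 (limma adjusted p = 0.138) and with a pseudocount of 0.1 (0.12). CD4 T cell markers had 2 of 6 lower (2 adjusted over the list alone, camera adjusted p = 0.862, direction down, median 0.18). No B cell marker of 5 passed (0 adjusted over the list alone, camera adjusted p = 0.662, direction up, median −0.10). Immediate early and heat shock genes had 6 of 23 higher and 8 lower (the same adjusted over the list alone, camera adjusted p = 0.993). Hspd1 stood at 299 ± 20.8 against 696 ± 27.1 CPM. Mitochondrially encoded mRNAs had 3 of 13 lower and none higher (3 adjusted over the list alone, camera adjusted p = 0.752). The counts were 4 higher and 3 lower both with median-of-ratios scaling, where the median log2 fold change was 0.103 in place of −0.005, and with edgeR. Without KO day 5 replicate 2, the library with the low mitochondrial share, they were 5 and 3. Klrb1c, the single tested marker of the gamma delta, MAIT and NKT list, rose to 13.3 ± 2.82 CPM from 0.761 ± 0.660. Of the 2 tested stromal and endothelial markers Thy1 rose and Pecam1 did not pass.

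**Figure D3:**
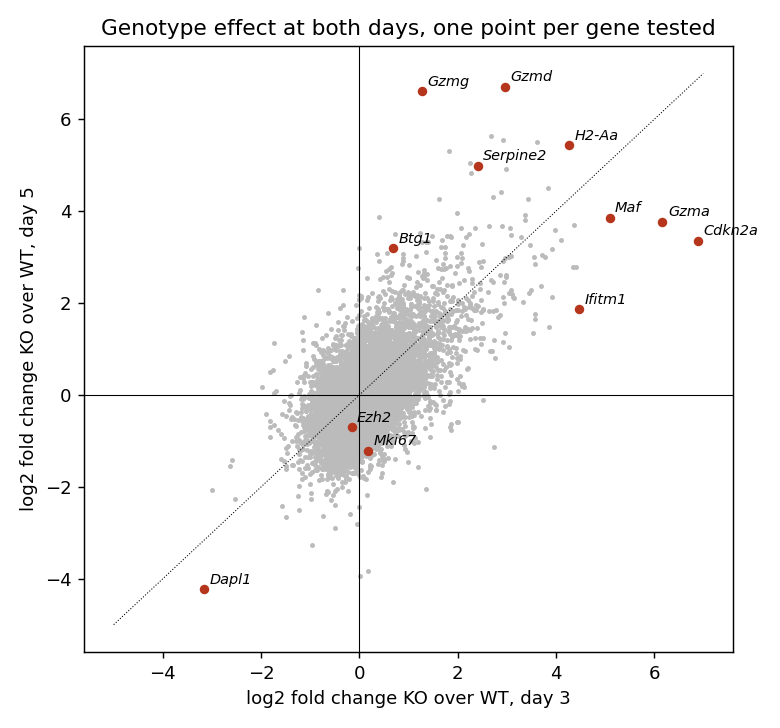
Log2 fold change of KO over WT at day 3 (horizontal axis) and day 5 (vertical axis), one point for each of the 11417 genes tested, with named genes in red. Cdkn2a and Gzma lie below the dotted line of equal change and Gzmg, Gzmd, Serpine2 and Btg1 above it.

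The genotype effects at the 2 days, which share no library, were set side by side. Of the genes higher in KO, 1275 at day 3 and 1885 at day 5, 827 were called at both days where independent calls would share 211 (odds ratio 15.8, one-sided Fisher's exact test, log10 p = −390.8). Of those lower, 825 and 2616, 598 were shared where 189 would be (odds ratio 11.2, log10 p = −219.2). Only 32 genes higher at day 3 were lower at day 5, and 25 the reverse. Across genes the log2 fold changes correlated with Pearson's r = 0.621 and Spearman's rho = 0.549. These values and the Fisher tests describe genes, which are not independent replicates, so the Fisher p-values are not to be read as strength of evidence. Both comparisons also share each gene's spread estimate, so calls at the 2 days are not independent even though no library is shared.

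Whether the genotype effect itself differed between the days was tested as an interaction. Cell cycle genes had a more negative genotype effect at day 5 than at day 3. Mki67 was at 896 ± 44.8 CPM in KO and 795 ± 21.6 in WT at day 3 and at 416 ± 29.1 against 963 ± 56.5 at day 5 (interaction −1.38 ± 0.10 SE, limma adjusted p = 2.36e-08). The tubulin gene Tuba1b was at 2724 ± 165 against 3253 ± 103 and at 1006 ± 43.6 against 2863 ± 63.3. The antiproliferative gene Btg1 rose in KO from 199 ± 37.8 at day 3 to 1194 ± 7.43 CPM at day 5, while WT stood at 122 ± 4.39 and 130 ± 10.3 (2.51 ± 0.15 SE, limma adjusted p = 4.09e-10). Ifi27l2a was lower in KO at day 3 (36.7 ± 6.17 against 126 ± 3.10 CPM) and higher at day 5 (166 ± 40.7 against 111 ± 14.7). Ifitm1 and Ifitm2 had larger genotype differences at day 3 than at day 5 (interaction −2.61 ± 0.15 and −1.96 ± 0.16 SE), as WT levels of Ifitm1 rose from 42.2 ± 7.92 to 716 ± 49.6 CPM.

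The interaction passed for 1468 genes, 458 with a positive and 1010 with a negative coefficient. The share positive was 31.2% with the deposited scale, 45.4% with median-of-ratios scaling (617 and 742 genes), 42.8% with quantile normalisation and 37.1% with edgeR. Of 23 lists 16 passed camera, and 5 with an estimated correlation. The 5 were the S and G2/M genes (42 of 45 negative, 45 adjusted over the list alone, camera adjusted p = 5.91e-41, adjusted p = 0.00103 with an estimated correlation), cholesterol synthesis genes (20 of 28 negative, 23 adjusted over the list alone, 6.14e-16 and 2.96e-04), p53 response genes (10 of 26 positive, 10 positive and 2 negative adjusted over the list alone, 1.52e-06 and 0.00326), memory precursor genes (8 of 29 positive and 2 negative, 12 and 5 adjusted over the list alone, 4.03e-04 and 0.0197) and myeloid markers (3 of 17 positive and 1 negative, 4 and 1 adjusted over the list alone, 6.47e-04 and 0.0197; 5 positive with quantile normalisation and none with edgeR). The number of p53 response genes with a positive coefficient was 6 without KO day 3 replicate 1 or WT day 3 replicate 1. In the memory list Tcf7, encoding TCF-1, stood at 16.4 ± 3.47 CPM in KO against 32.2 ± 3.69 in WT at day 3 and at 61.3 ± 4.26 against 40.3 ± 9.35 at day 5 (1.55 ± 0.26 SE, limma adjusted p = 2.95e-04). Il7r, Bach2 and Ltb turned the same way, from lower in KO at day 3 to higher at day 5. Terminal effector genes did not differ as a list (5 of 31 positive and 6 negative, 5 and 7 adjusted over the list alone, camera adjusted p = 0.927), with Gzma at −2.40 ± 0.23 SE. The number positive was 1 without KO day 3 replicate 2 and 3 without WT day 3 replicate 3 or WT day 5 replicate 2. Cytotoxic genes had 6 of 23 positive and 2 negative (6 and 3 adjusted over the list alone, camera adjusted p = 0.0235, adjusted p = 0.32 with an estimated correlation). Among them Gzmg and Gzmd, at or near 0 in WT, passed on the log2(CPM + 1) scale and not with edgeR (log2 fold changes of 5.669 and 1.702, adjusted p of 1.00 and 0.857), and Gzmd did not with a pseudocount of 0.1 (3.082, 0.0791). With edgeR 1 member of the list was positive.

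WT cells were compared between days to give the change without genotype. Ifitm1 rose 17.0-fold and Cdkn2a 18.9-fold, from 3.77 ± 2.57 to 71.2 ± 6.62 CPM, Gzma 9.92-fold, Serpina3f 11.7-fold, Ifit1bl1 13.8-fold and S100a4 7.38-fold. The cytokine gene Lif fell 7.17-fold, Dennd5b 7.16-fold, the adenylate kinase gene Ak4 3.82-fold and Tnfrsf4 3.74-fold. Cholesterol synthesis genes had 17 of 28 higher at day 5 and none lower (21 adjusted over the list alone, camera adjusted p = 9.28e-14, adjusted p = 4.78e-04 with an estimated correlation). They included Hmgcs1 (470 ± 24.4 to 794 ± 20.6 CPM). Terminal effector genes had 15 of 31 higher and 1 lower (16 and 2 adjusted over the list alone, camera adjusted p = 2.10e-10, adjusted p = 0.0159 with an estimated correlation), and trafficking genes 10 of 26 higher and 2 lower (11 and 2 adjusted over the list alone, 4.30e-05 and 0.0159), with 6 higher without WT day 3 replicate 2. Myeloid and dendritic cell markers had 5 of 17 higher and none lower (5 adjusted over the list alone, 0.00797 and 0.0495), with 3 higher without WT day 5 replicate 2. Their list call ended with no expression filter (camera adjusted p = 0.0585). Glycolysis genes had 11 of 31 lower and 2 higher (13 and 2 adjusted over the list alone, 3.02e-09 and 0.0243), and immediate early and heat shock genes 11 of 23 lower and 4 higher (12 and 4 adjusted over the list alone, 9.50e-05 and 0.0159). Hk2 fell from 324 ± 10.5 to 148 ± 4.96 CPM and Hspa8 from 2147 ± 16.4 to 1342 ± 71.5. S and G2/M genes had 9 of 45 lower and 3 higher, among the latter Mki67 (14 and 4 adjusted over the list alone, 6.21e-05 and 0.129). Without KO day 5 replicate 2 there were 15 lower and 4 higher, without WT day 3 replicate 2 there were 5 lower, and without WT day 3 replicate 1 or 3 or WT day 5 replicate 1 or 2 there were 4 lower. The Mki67 call ended under 6 alternatives, namely a fit without the trend in the spread (limma adjusted p = 0.141), median-of-ratios scaling (0.054) and leaving out WT day 3 replicate 1 or 2 or WT day 5 replicate 1 or 3 (0.0863, 0.0531, 0.103 and 0.0594). Of 23 lists 10 passed camera, and 6 with an estimated correlation. In total 1249 genes differed, 819 higher and 430 lower. The share higher was 65.6%, and 55.5% with median-of-ratios scaling (678 and 543 genes). A fit of the spread without its trend on expression left 773 calls, and leaving out WT day 5 replicate 3 left 818.

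KO cells were compared between days in the same way, and 4006 genes differed, 1759 higher and 2247 lower at day 5 (1992 and 2026 with median-of-ratios scaling). Of 23 lists 15 passed camera, and 9 with an estimated correlation. Gzmg rose 52.6-fold, Klhl30 26.1-fold, Gzmd 19.7-fold, Ly6g 18.7-fold and the chemokine receptor gene Xcr1 11.6-fold, to 68.0 ± 0.612 CPM. Taf6 fell 10.0-fold, Dnph1 6.91-fold, Nt5dc2 6.82-fold and Chchd10 5.80-fold. All 45 S and G2/M genes fell (45 adjusted over the list alone, camera adjusted p = 2.07e-34, adjusted p = 0.00383 with an estimated correlation), the nucleotide synthesis gene Rrm2 from 217 ± 7.75 to 57.1 ± 5.49 CPM. Glycolysis genes had 24 of 31 lower and 3 higher (25 and 3 adjusted over the list alone, 3.54e-09 and 0.0228) and cholesterol synthesis genes 13 of 28 lower and 2 higher (the same adjusted over the list alone, 0.00226 and 0.0228). Memory precursor genes had 15 of 29 higher and 3 lower (17 and 6 adjusted over the list alone, camera adjusted p = 8.42e-04, adjusted p = 0.0228 with an estimated correlation). Tcf7 moved from 16.4 ± 3.47 to 61.3 ± 4.26 CPM and Bach2 from 28.5 ± 4.57 to 76.7 ± 15.0. Terminal effector genes had 17 of 31 higher and 3 lower (18 and 3 adjusted over the list alone, 1.01e-06 and 0.0255). S100a4 moved from 579 ± 79.5 to 2094 ± 355 CPM. p53 response genes had 12 of 26 higher and 2 lower (14 and 2 adjusted over the list alone, 1.16e-04 and 0.0142). Bbc3, encoding PUMA, moved from 15.2 ± 2.21 to 69.1 ± 13.9 CPM. Myeloid and dendritic cell markers had 13 of 17 higher and none lower (14 adjusted over the list alone, 6.22e-07 and 0.00476). Oxidative phosphorylation genes had 22 of 37 lower and 1 higher (23 and 2 adjusted over the list alone, 7.47e-06 and 0.0356) and trafficking genes 13 of 26 higher and 3 lower (14 and 3 adjusted over the list alone, 2.51e-04 and 0.0228). Mitochondrially encoded mRNAs had 11 of 13 lower and none higher (11 adjusted over the list alone, 1.56e-04 and 0.244), and 10 lower without KO day 5 replicate 2, the library with the low mitochondrial share. Cdkn2a, at 518 ± 49.2 and 737 ± 60.2 CPM, did not pass (limma adjusted p = 0.0759), but passed with median-of-ratios scaling, quantile normalisation, a pseudocount of 5, a fit to the KO libraries only, or edgeR.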

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

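The thinning, the ratio of calls without KO day 5 replicate 2 (leaving out each library was itself planned), the search for transcripts of other cells and the exchange of genotypes at one day were tests chosen only after the results were seen. Each gene or list given here differed between the days in its genotype effect, by the interaction test.

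The genes with a more positive KO effect at day 5 were Btg1 (interaction 2.505), Serpine2 (2.579), Ifi27l2a (2.313), Npc2 (1.255) and Gimap3 (1.44), on the log2(CPM + 1) scale. Those with a more negative effect at day 5 were Ifitm1 (−2.607), Ifitm2 (−1.963), Mki67 (−1.383), Tuba1b (−1.252) and Top2a (−1.153). Npc2 stood at 312 ± 9.76 CPM in WT and 322 ± 46.5 in KO at day 3, and at 411 ± 18.5 and 1009 ± 58.2 at day 5. List medians of the interaction were 0.385 for memory precursor genes, −1.139 for S and G2/M genes, 0.589 for p53 response genes, −0.953 for cholesterol synthesis genes and 0.794 for myeloid and dendritic cell markers. Of the 17 tested myeloid markers 3 were positive and 1 negative, and the number positive depended on the test, as given with the interaction. Members near 0 in WT, such as H2-Aa with 1 read at each day, give no measured ratio of KO to WT.

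KO day 5 replicate 2 stood apart from its group. WT cells in that library, or a wrong label, would pull it towards WT, but its slope on the axis from WT to KO was 0.896, between those of the other KO day 5 libraries (0.882 and 0.913). Ezh2 itself went the other way, at 283 CPM in this library, 159 and 161 in its partners and 306 to 319 in WT day 5. Mitochondrial genes, pseudogenes and predicted models do not account for the distance of this library from its partners. Without them the chi-square per degree of freedom of its pairs was 4.91 and 5.18, against at most 2.43 elsewhere. Protein-coding near copies such as Gzmd to Gzmg were not removed, so reads shared among those stay untested. A difference in culture, animal or library preparation of that sample may remain, and no value here tests it.

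More genes were called between genotypes at day 5 than at day 3, and all 45 tested S and G2/M genes were lower in KO. Fewer reads in the KO day 5 libraries would lower the number of calls there, so the ratio of 2.22 after thinning was close to fixed by the design and decides nothing. Under median-of-ratios scaling 45 of these genes were still lower. Its factors ran from 0.9419 to 1.041 in the day 5 libraries, too near each other to undo a list median of −1.355. The fall thus does not depend on which of these scalings is used, and a change in total RNA per cell was not measured. Without the library that stands apart there were still more calls at day 5 than at day 3 (4415 against 2705, a ratio of 1.63). With all libraries the counts were 4501 and 2100. The ratio without that library was thus lower mainly because day 3 calls rose, while day 5 calls changed little. That library is not part of the day 3 comparison, but all groups share each gene's spread estimate in the fit. A lower share of dividing cells in KO at day 5 may be behind the lower cell cycle genes, and it was not measured.

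MHC class II and myeloid marker genes were higher in KO. B cells, monocytes or macrophages in the KO cultures would bring their other abundant transcripts, but in KO day 5 those summed to 8 reads against 1127 of MHC class II genes, a ratio of 0.0071 (0 and 330 in WT day 5, 326 of the latter from H2-Ab1). Of the 1127 reads 501 came from H2-Ab1. The sum holds genes such as Lyz2, C1qa, S100a8, Cd79a and Csf1r. It leaves out Ly6g and Fcer1g, which were higher in KO at day 5, so it covers only the transcripts chosen. At day 3 the KO libraries held 20, 18 of them from Csf1r, and 659, and the WT libraries 1 and 232. Immunoglobulin genes are not in the sum, since of 494 immunoglobulin and T cell receptor genes 0 had a read in these T cell libraries, so such genes appear not to have been counted. Among dendritic cell markers, Siglech had 0 reads in every group and Flt3 had 2 reads in KO day 3 and 0 in KO day 5. Xcr1, which is on the same list, went the other way and rose in KO between the days. Dendritic cells stay open, and expression of the MHC class II and myeloid marker genes by the T cells may be the source, which was not tested.

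For each genotype comparison and each day comparison, 1 of the 10 splits of its 6 libraries, the real one, gave as many calls. The real splits gave 2100 and 4501 calls for genotype at days 3 and 5 and 1249 and 4006 for day in WT and KO, and the highest of the other splits 0, 0, 0 and 1. With 10 splits a share under 0.05 cannot be had. Each other split also mixes the real groups, which puts their difference into the spread. Few calls there were thus close to fixed in advance and decide nothing about chance. For the interaction, 4 of 100 drawn relabellings, the real one included, gave as many calls as the real 1468, with 2523 the highest other. The 3 larger ones each differ by 1 pair of libraries from an exchange of the genotypes at one day, which alone gives 4893 calls, and point to the genotype difference itself as the structure of these libraries. Such relabellings carry that difference into the interaction and into the spread, so they do not stand for libraries without an interaction, and whether chance can be excluded stays open by this measure.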

How the results depend on the processing

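The edgeR test, thinning and counts of list members without each library were chosen after seeing the data. No test was run on deposited counts, since the files hold none, and edgeR was run on the recovered reads. Depth limits what can be seen, since 1 read is worth 0.497 to 0.647 CPM.

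Counts of genes called between genotypes stayed within 1.5 times under every scaling, filter, pseudocount and moderation tried. Leaving out each library in turn gave 1493 to 2705 calls at day 3 (2100 with all), 3879 to 4484 at day 5 (4501), 818 to 1775 for day in WT (1249), 3332 to 3950 for day in KO (4006) and 1112 to 1761 for the interaction (1468). The lowest value for day in WT was without WT day 5 replicate 3, and 822 remained without WT day 3 replicate 1. With edgeR the calls were 2105, 4359, 1292, 3967 and 1357, and after thinning 1946, 4319, 1165, 3803 and 1362. Requiring 2-fold left 767, 1715, 308, 1311 and 532, by construction. Without the trend in the spread, day in WT had 773 calls and the interaction 884, and the cause was not tested. With an estimated correlation, 7 lists passed for genotype at day 3, 6 for day in WT, 9 for day in KO and 5 for the interaction. With fry 16 and 20 lists passed for genotype at days 3 and 5. The fry counts were 11 and 20 for day in WT and KO and 14 for the interaction.

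The correlation of genotype effects between the days (0.621, jackknife SE 0.0259) was 0.567 with a pseudocount of 0.1, 0.647 with one of 5, 0.595 with no filter, 0.672 with a filter of 5 CPM, 0.57 with edgeR and 0.587 to 0.617 leaving out each library, lowest without KO day 3 replicate 3. Ezh2 kept its direction and its side of the threshold at both days under each alternative tried. Pecam1, not called at day 5, had log2 fold changes from −0.028 without KO day 5 replicate 1 to 0.347 without KO day 5 replicate 2.

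Camera calls on single lists moved with the settings, and the cause was not tested. Values are adjusted p. With a pseudocount of 0.1, list calls were lost for genotype at day 3 (CD4 0.0535), day in KO (immediate early 0.0692) and interaction (PRC2 0.0517, H3K27me3-linked 0.0617, cytotoxic 0.177, NK receptor 0.0654). The pseudocount of 0.1 turned directions for day in WT (p53 response 1, CD4 1) and interaction (trafficking 0.976, B cell 0.964, erythroid 0.976). With a pseudocount of 5, list calls were lost for genotype at day 3 (oxidative phosphorylation 0.0552, CD4 0.0552, erythroid 0.0624) and interaction (H3K27me3-linked 0.108). The pseudocount of 5 added calls for genotype at day 5 (memory precursor 0.0452, erythroid 0.0402) and day in KO (inhibitory receptor 0.0302). The pseudocount of 5 turned directions for genotype at day 5 (immediate early 0.926), day in WT (CD4 0.989) and interaction (terminal effector 0.92, helper 0.92). With no expression filter, list calls were lost for genotype at day 3 (CD4 0.0501, erythroid 0.055), day in WT (H3K27me3-linked 0.592, myeloid 0.0585) and interaction (H3K27me3-linked 0.745). The missing filter added calls for day in KO (inhibitory receptor 0.047). The missing filter turned directions for genotype at day 5 (immediate early 0.935), day in WT (CD4 0.977) and interaction (helper 0.776, B cell 0.745). With a filter of 5 CPM, list calls were lost for genotype at day 3 (oxidative phosphorylation 0.0895, CD4 0.238), day in KO (immediate early 0.117) and interaction (PRC2 0.0662, H3K27me3-linked 0.105). The 5 CPM filter added calls for genotype at day 3 (inhibitory receptor 0.0184), genotype at day 5 (memory precursor 0.0267, erythroid 0.0262) and day in KO (inhibitory receptor 0.0418). The 5 CPM filter turned directions for genotype at day 5 (immediate early 0.877, CD4 0.891). With median-of-ratios scaling, list calls were lost for genotype at day 3 (oxidative phosphorylation 0.0624) and interaction (PRC2 0.0679). The median-of-ratios scaling added calls for genotype at day 5 (memory precursor 0.0383). The median-of-ratios scaling turned directions for genotype at day 5 (immediate early 0.938, mitochondrial 0.852) and interaction (terminal effector 0.964). With quantile normalization, list calls were lost for genotype at day 3 (cytokine 0.0617, oxidative phosphorylation 0.361, erythroid 0.0658) and interaction (PRC2 0.0834). The quantile normalization added calls for genotype at day 5 (memory precursor 0.0262). The quantile normalization turned directions for genotype at day 5 (immediate early 0.844) and day in WT (p53 response 0.997, mitochondrial 0.951, CD4 0.997, CD8 0.997). With no trend in the spread, list calls were lost for genotype at day 3 (oxidative phosphorylation 0.0593), day in KO (immediate early 0.118) and interaction (PRC2 0.0815). The missing trend added calls for genotype at day 5 (erythroid 0.0318) and day in KO (inhibitory receptor 0.023). The missing trend turned directions for day in WT (p53 response 0.987) and interaction (terminal effector 0.743, helper 0.865). With only the libraries compared, list calls were lost for genotype at day 3 (cytokine 0.0551, CD4 0.0662, erythroid 0.0621), day in WT (H3K27me3-linked 0.0771) and day in KO (immediate early 0.059). The smaller fit added calls for genotype at day 5 (erythroid 0.0363) and day in KO (inhibitory receptor 0.0327). The smaller fit turned directions for day in WT (p53 response 0.95, CD4 0.975, CD8 0.975).

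Leaving out each library in turn, list adjusted p ranged for day in WT over B cell 0.448 to 0.961, CD4 0.819 to 0.999, p53 response 0.812 to 0.999. For interaction the ranges were B cell 0.687 to 0.995, CD4 0.0387 to 0.149, cytotoxic 0.00403 to 0.112, H3K27me3-linked 0.0344 to 0.0962, helper 0.714 to 0.995, PRC2 0.0119 to 0.0769, terminal effector 0.505 to 0.986, trafficking 0.706 to 0.988. For day in KO the ranges were CD4 0.0486 to 0.163, immediate early 0.0306 to 0.0749, inhibitory receptor 0.0311 to 0.101, PRC2 0.0276 to 0.117. For genotype at day 3 the ranges were CD4 0.0298 to 0.0881, cytokine 0.0109 to 0.0595, erythroid 0.00683 to 0.0862, oxidative phosphorylation 0.0172 to 0.131. For genotype at day 5 the ranges were CD4 0.705 to 0.929, CD8 0.00502 to 0.112, erythroid 0.0308 to 0.116, immediate early 0.839 to 1, memory precursor 0.0296 to 0.0753, mitochondrial 0.226 to 0.95.

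The labels give the groups the same replicate numbers, but same-numbered libraries deviated with correlations of −0.0138 to 0.0422, and 5 of 12 libraries correlated best with their own number. No pairing is seen in these values, but read sampling adds to such deviations and could hide one, so pairing stays open. With the number as a block there were 2072, 4487, 1238, 3991 and 1473 calls and 1413 shared between the days. With the replicate block, list calls were lost for genotype at day 3 (oxidative phosphorylation 0.0521, CD4 0.0521), day in KO (immediate early 0.0518) and interaction (H3K27me3-linked 0.0572). The block added calls for genotype at day 5 (memory precursor 0.0441) and day in KO (inhibitory receptor 0.0498). The block turned directions for day in WT (CD4 0.999).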

Other observations

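The gene families in the next paragraph were chosen after the data were seen and are described without a list test, and the test of day 3 against the change in WT was planned before its result was seen.

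Gimap genes, which encode small GTPases of lymphocyte survival, were higher in KO at day 5 in 8 of 8 tested members against 1 at day 3. Gimap6 stood at 174 ± 11.7 CPM in KO and 66.2 ± 1.44 in WT at day 5. Cytosolic aminoacyl-tRNA synthetase genes rose with time in WT in 9 of 17 members and were lower in KO at day 5 in 15 of 17. Gars stood at 211 ± 24.4 against 316 ± 1.55 CPM. Proteasome subunit genes were lower in KO at day 5 in 31 of 37, for example Psmb5 (148 ± 20.3 against 229 ± 5.43 CPM). Chaperonin subunit genes were lower in 6 of 7 (5 with median-of-ratios scaling or quantile normalization). Mitochondrial ribosomal protein genes had 37 of 75 lower and 2 higher, but 29 and 6 with median-of-ratios scaling and 30 and 6 with quantile normalization. Median-of-ratios scaling kept the direction of these medians, with 8, 14 and 30 members called at day 5 in the Gimap, synthetase and proteasome families. Cytosolic ribosomal protein genes had 32 of 78 higher and 1 lower at day 5, but 47 and 1 with median-of-ratios scaling and 18 and 9 with quantile normalization, so their count depends on the scaling.

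A hypothesis is that KO cells at day 3 hold part of the change that WT cells make between the days. Both changes are taken against the WT day 3 libraries, and their log2 fold changes correlated across genes with r = 0.425, where unchanged groups sharing those libraries gave 0.499 in simulation. The covariance was 0.121 against 0.0478 simulated. With the WT day 3 libraries divided so that no library was shared, the lowest of 3 correlations was 0.217 (0.232 and 0.241 in the others). Of 1275 genes higher in KO at day 3, 358 rose with time in WT where independent lists would share 91.5, and of 825 lower, 128 fell where 31.1 would. The opposite pairings shared 37 and 28 genes against 48 and 59.2. These values are consistent with the hypothesis for part of the change. They do not tell earlier progress in KO from a separate effect on the same genes, and part of the excess overlap may come from the shared libraries.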
